A study of Arabidopsis thaliana with 17 samples.

How the data were processed

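The series mapped open chromatin in Arabidopsis thaliana (Col-0 background) by DNase I sequencing, in which DNA that is not wrapped up by nucleosomes is cut by the enzyme and the short fragments between pairs of cuts are sequenced. Per the labels' protocols, nuclei were isolated by biotin capture from INTACT lines. In such a line, a nuclear envelope fusion protein (NTF) is made under a chosen promoter and biotinylated by the ligase birA, here under the ACT2 promoter. Per the labels, the UBQ10 promoter drove the fusion in whole roots and flowers, the GL2 promoter in non-hair cells of the root epidermis and in the seed coat, and the ADF8 promoter in root hair cells. Roots came from plate-grown seedlings of 7 or 10 days, seed coats from siliques 4 or 7 days past anthesis (DPA), and flowers were collected open or unopened. The 17 samples come from 16 libraries, because replicates 1 and 2 of the 4 DPA seed coat are runs of a single library and have identical deposited lists.

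The data used here are 22 deposited peak lists. Per the submitters' processing notes, Bowtie 0.12.7 and the genome build TAIR10 were used, with no role given for either. The peak caller and its threshold are not given in the sources used here. Signal tracks were not used here. Peaks span 150 bp in the marked lists and between 150 and 290 bp in the unmarked lists. Each carries a score, a height made by the authors that is a whole number in value (0 exceptions in any list), which was used only to rank or filter peaks within its own list. The full-depth lists also carry a deposited -log10 p per peak from the authors' peak caller, which was not used. There are 11 lists with the mark 6.8M, 3 with the mark 6.65M and 8 with no mark. The marks are read here as a common number of reads per list, which no label states in words, and the depth of the unmarked lists is unknown. The pooled lists combine reads of 2 libraries each, per the series design text: hair replicates 2 and 3, 4 DPA replicates 3 and 4, and 7 DPA replicates 1 and 2. Peaks on the chloroplast and mitochondrial sequences were left out of all comparisons.

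The lists hold no read counts, so the list was the unit of analysis and no counting error can be given for a single peak. A site is a merged interval of all peaks of the 11 lists at 6.8M (gap 0 bp), and a list has a site if a peak overlaps it by at least 1 bp. The 2 flower lists were merged in the same way on their own. A separating site is in every list of one group and in no list of the other. Groups were whole root (2 lists), non-hair (4), hair (2, of which 1 is pooled), seed coat 4 DPA (2, of which 1 is pooled) and seed coat 7 DPA (1 pooled list). Coordinates are TAIR10, counted from 1. Each site was assigned to the protein-coding gene with the nearest transcription start site (TSS) among 27444 genes, and its centre was placed, in this order, within 400 bp upstream of a TSS, in a 5-prime UTR, coding exon, intron or 3-prime UTR, or otherwise called intergenic. The rank percentile of a site is that of its highest peak by score in a list, 100 being the top, averaged over the lists of the group that holds it.

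Similarity between lists was the Jaccard index, the base pairs shared divided by the base pairs in either list. Mean similarity within groups minus between groups was tested by an exact one-sided permutation of the group labels. Counts of separating sites were set against all other splits of the same lists into groups of the same sizes, or 100 drawn splits where there were more. For seed coat against root, Fisher's exact test (two-sided) was also run at each site with Benjamini-Hochberg adjustment. For each gene list, the number of members with a separating site was compared with 10000 random lists matched on the number of sites per gene (1, 2, 3, 4 to 5, 6 or more), giving a one-sided permutation p, adjusted over the 32 tests of a comparison (16 lists in both directions). The background was every gene with a site in the comparison. Motif matches on either strand in the central 150 bp of a site were compared between directions by Fisher's exact test (two-sided), adjusted over 16 motifs. The G-box (CACGTG), ABRE (ACGTGKC) and root hair element core (KCACGW) share bases, so a single stretch can match several of them. Genes and sites are not replicates, so these p values describe the lists. The 4 DPA against 7 DPA comparison has a single list on the 7 DPA side and the flower comparison a single list on each side. They are therefore given as counts, percentiles among the random lists and exact 95% binomial (Clopper-Pearson) intervals, which cover counting error over sites only.

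The 16 gene lists, the 16 motifs and the rule for named genes were fixed before the data were examined. The lists hold genes of root hairs, non-hair fate, class IV HD-ZIP factors, inner root tissues, root meristem and cap, mucilage and seed coat epidermis, proanthocyanidin, embryo and storage, endosperm, silique wall, photosynthesis, floral organs, tapetum and meiosis, late flower and pollen, constitutive genes and the transgene promoters. A further list of 13 embryo maturation genes was added for a test in the closing section. The rule names, per comparison, at most 8 members of each list with a separating site, in order of mean rank percentile, the 8 separating sites of best mean rank per direction within 2000 bp of a TSS, and always GL2, ADF8, UBQ10 and ACT2. From these the text gives examples. For the transgene promoters, the best peak between 3000 bp upstream and 500 bp downstream of the TSS was taken in each list.

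Alternatives were overlap of at least 50% of a peak, the best 12375 peaks of each list, the same number of peaks in every list, peaks within 100 bp merged, each list left out, pooled lists left out, 7-day seedlings only, 4 DPA lists only, the 6.65M lists, presence in at least 3 of 4 non-hair lists, Jaccard by site, assignment to genes from 1000 bp upstream to the 3-prime end, no matching of random lists, motifs in the whole site or against sites in every list, and full-depth lists. Alternatives chosen after seeing the data were separating sites in the upper ranks only and absence also from the full-depth lists of the other group. A separating site is in the upper ranks if its percentile is at least 50 in each list of the group that holds it. A further such alternative left out sites matching organelle sequence (at least 50% of their 31-base words). Also chosen after seeing the data was a count of separating sites with a peak of the other group within 100 bp. Simulated lists kept the number of sites of each real list, with sites drawn at random in proportion to how often they occur. With none planted, 40 seed coat-only and 13 root-only sites appeared among 49442 sites. All 200 planted separating sites were recovered, which the definition of a separating site ensures, so this checks only the code. On the real sites of seed coat against root, 7 of 200 random gene lists had an unadjusted p under 0.05 (permutation, one-sided). By calculation, the per-site Fisher's test needs at least 5993 separating sites to call any. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.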

Results

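Open chromatin was compared between cell types and stages of Arabidopsis thaliana through peaks of DNase I cutting. At the 6.8M mark the lists held 26837 and 26671 peaks for whole root replicates 1 and 2, and 26380, 25953, 26947 and 29089 for non-hair replicates 1 to 4 (mean 27092 ± 1392, SD, n = 4). Hair replicate 1 had 24751 peaks and the hair pool 25103. In the seed coat there were 30110 peaks at 4 DPA (replicate 1), 28362 in the 4 DPA pool and 27036 in the 7 DPA pool. The pooled lists have no replicate of their own. At full depth, with the number of reads unknown, open flowers gave 11748 peaks and unopened flowers 13098. Peaks of the 6.8M lists covered between 3.12% and 3.79% of the 5 nuclear chromosomes, and between 62.5% and 66.9% of them lay within 1 kb of a TSS. The 11 lists merged into 49442 sites, of which 10683 (21.6%) were in every list and 8950 (18.1%) in a single list.

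On average, lists from the same group overlapped more than lists from different groups, and the deepest divide was between seed coat and root. The mean Jaccard index was 0.456 within groups and 0.336 between groups, where 4 and 7 DPA seed coat count as different groups. The difference of 0.119 was reached by 24 of 207900 labellings (exact permutation, one-sided, p = 0.000115). Between root and seed coat groups the mean index lay between 0.253 and 0.289, and the real division into 8 root and 3 seed coat lists gave the largest difference of all possible divisions (exact permutation, one-sided, p = 0.00606, the smallest possible). Within the root, the difference was 0.0444 (exact permutation, one-sided, p = 0.019). Between hair and non-hair lists the mean index was 0.428, against 0.450 within the groups (0.515 for the pair of hair lists and 0.439 among the non-hair lists), and the highest index between a hair and a non-hair list was 0.480. As large a difference came from 4 of 15 labellings (exact permutation, one-sided, p = 0.267). The smallest p that 15 labellings can give is 0.0667, so this test could not have passed 0.05. The pair of whole root lists, at 0.428, overlapped no more than whole root with hair lists (mean 0.430). The 4 DPA lists overlapped each other at 0.525 and the 7 DPA pool at 0.434.

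**Figure D1:**
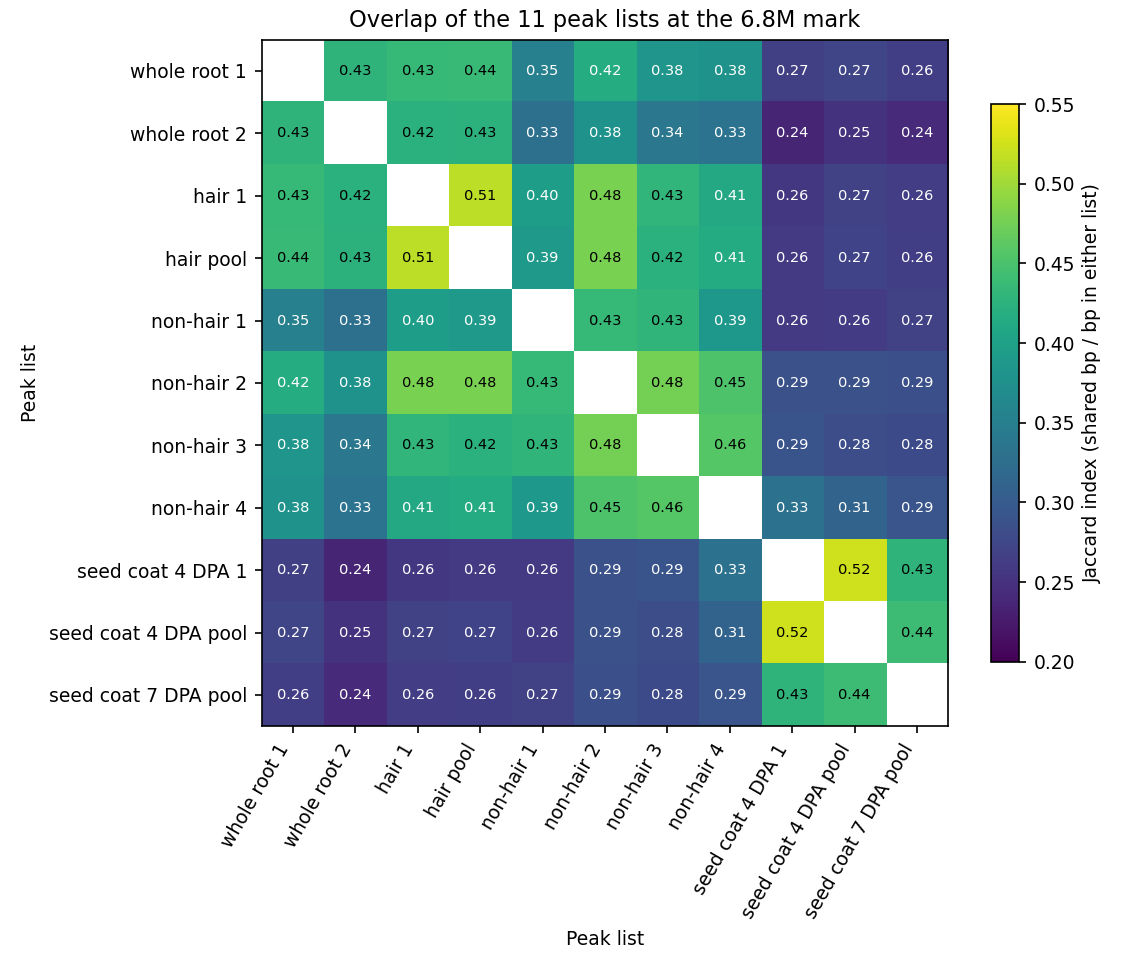
Jaccard index (shared bp divided by bp in either list) for each pair of the 11 peak lists at the 6.8M mark, with lists on both axes and the index as colour. Root lists share between 0.329 and 0.515 with each other and less with the seed coat lists, between 0.236 and 0.331.

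The comparison of seed coat with root asks which regulatory DNA is open in the captured seed coat cells and closed in the root, and the reverse. Genes of proanthocyanidin synthesis, floral organ identity and photosynthesis carried more seed coat-only sites than random gene lists, and root hair genes carried more root-only sites. All 3 seed coat lists and none of the 8 root lists had a peak at 2969 sites, and 3041 sites showed the reverse. Seed coat-only sites lay at a median rank percentile of 48.1 and root-only sites at 63.2, against 68.3 and 63.9 for the sites found in all lists. A root-only site must have a peak in all 8 root lists and a seed coat-only site in 3. Agreement of more lists can favour higher-ranked peaks, so these medians do not compare the directions on equal terms.

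Among the proanthocyanidin genes, which make the brown pigment of the inner seed coat layer, 7 of 13 had a seed coat-only site against 1.88 on average in random lists (adjusted p = 0.0112, permutation, one-sided). The highest-ranked site lay near TT7 (AT5G07990), the flavonoid 3-prime hydroxylase, at chromosome 5, 2558121 to 2558330, intergenic, at percentile 98.7. The regulators of this pathway followed, with the zinc finger gene TT1 at 55.5, the MADS box gene TT16 at 52.9, the bHLH gene TT8 at 45.2 and the MYB gene TT2 at 39.5. The TT2 site (chromosome 5, 13726621 to 13726790) lay within 400 bp upstream of the TSS, as did those of the laccase gene TT10 and the glutathione transferase gene GSTF12. No proanthocyanidin gene had a root-only site.

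Floral organ genes had a seed coat-only site in 12 of 23 members (random mean 4.85, adjusted p = 0.0112, permutation, one-sided): AG, AP3, BOP2, ETT, HEC1, SEP1, SEP2, SEP3, SEP4, SPL, SPT and SUP. The AP3 site (AT3G54340, chromosome 3, 20121241 to 20121490, within 400 bp upstream of the TSS) stood at percentile 94.0, and that of SEP2 (AT3G02310, chromosome 3, 467761 to 467970, intergenic) at 92.4. AG (AT4G18960), the carpel and stamen identity gene, had an intergenic site at chromosome 4, 10381161 to 10381370, at percentile 91.2. ETT and BOP2 also had root-only sites at other positions, as did BEL1, BOP1 and JAG, so that 5 of 23 members had one (random mean 5.38), that of BEL1 with a seed coat peak 90 bp away.

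Photosynthesis genes had a seed coat-only site in 9 of 30 members (random mean 3.14, adjusted p = 0.0192, permutation, one-sided), and 1 member, HEMA1, had a root-only site. These were RBCS1A and RBCS3B, which encode small subunits of Rubisco, the light-harvesting genes LHCA1, LHCA2, LHCB2.1, LHCB3, CAB1 and CAB2, and the photosystem I gene PSAH2. The RBCS1A site lay in the 5-prime UTR (AT1G67090, chromosome 1, 25049361 to 25049590) at percentile 74.6, while CAB1 and LHCB3 stood at 28.6 and 25.9.

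Root hair genes had a root-only site in 10 of 29 members (random mean 3.83, adjusted p = 0.0192, permutation, one-sided): CSLD3, ERU, EXPA7, EXPA18, LRL1, MRH1, RHD2, RSL3, RSL4 and XTH14. A root-only site of ERU had a seed coat peak 50 bp away. The site of the receptor kinase gene MRH1 (AT4G18640, chromosome 4, 10259101 to 10259470, within 400 bp upstream of the TSS) had percentile 97.6. The bHLH gene RSL3, a regulator of hair growth, had a site at chromosome 2, 6321181 to 6321670, at 87.2. RHD2, the NADPH oxidase of the growing hair tip, had an intron site at chromosome 5, 20758781 to 20759170, at 85.2. The expansin genes EXPA18 and EXPA7 had sites within 400 bp upstream of the TSS at 81.3 and 57.7. LRL1 was the 1 root hair gene with a seed coat-only site as well.

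Mucilage and seed coat epidermis genes did not pass the test, with seed coat-only sites at 10 of 30 members (random mean 6.08, adjusted p = 0.289, permutation, one-sided). Single members had sites at high percentiles, but the ranks of the list as a whole were not tested. MYB61, a regulator of mucilage, had one at chromosome 1, 3084641 to 3084790, at percentile 97.8, the ovule identity gene STK one at chromosome 4, 6242501 to 6242790, at 96.5, and the subtilase gene SBT1.7 one at chromosome 5, 26875721 to 26875970, at 95.5. MYB61, GAUT11 and NAC2, a NAC factor gene, also had a root-only site, as did AP2 (4 of 30 members, random mean 6.81). BXL1, a mucilage-modifying xylosidase gene, had an intron site at percentile 96.5 with a root peak 10 bp away.

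Other lists were not called for seed coat-only sites. Silique wall genes had 4 of 8 (random mean 1.33, adjusted p = 0.165, permutation, one-sided), namely the valve margin genes SHP1, SHP2 and ALC and the replum gene RPL. The SHP2 site, in the 5-prime UTR at chromosome 2, 17820061 to 17820230, stood at percentile 92.2. Root meristem and cap genes had 3 of 8 (PLT1, PLT2 and ACR4), HD-ZIP IV genes 4 of 13 (ATML1, PDF2, HDG1 and HDG2), and non-hair fate genes 4 of 14 (EGL3, ETC3, TRY and GL3). Inner root tissue genes had 5 of 31 against 6 of 31 with a root-only site, among them SGN3 and MYB46. The remaining lists had few: embryo and storage genes 2 of 13, endosperm genes 1 of 6, tapetum and meiosis genes 2 of 10, late flower and pollen genes 2 of 12, constitutive genes 1 of 9 and transgene promoters 0 of 4.

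By rank alone, the seed coat-only sites were led by NTMC2T2.1 (AT1G05500, chromosome 1, 1624161 to 1624310, intergenic, percentile 99.7), an intron site of AT3G61950 (chromosome 3, 22939641 to 22939790, 99.5) and sites near AT1G75580, bZIP70, AT3G57800, SCPL34, TLP5 and DSEL. The root-only sites were led by AT1G53620 (chromosome 1, 20012561 to 20012830, 99.1), AT2G44010, GH3.17, an auxin-conjugating enzyme gene (chromosome 1, 9824201 to 9824670, 98.6), AT1G70750, AT3G05165, the MYB factor gene MYB45, the polyol transporter gene PMT5 and AT3G46280. Of these best 8 in each direction, 1 (SCPL34) had a peak of the other group within 100 bp, as did 10.07% of all seed coat-only and 7.43% of all root-only sites.

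The W-box, bound by WRKY factors, was in 42.5% of root-only sites and 12.4% of seed coat-only sites (Fisher's exact, two-sided, adjusted p = 3.93e-156), with 23.6% in the sites of all lists. Seed coat-only sites more often held the CArG box of MADS factors (4.04% against 0.789%, Fisher's exact, two-sided, adjusted p = 7.63e-17), the site II element of TCP factors (9.16% against 3.72%, adjusted p = 2.45e-17), the G-box (6.53% against 2.37%, adjusted p = 9.37e-15), the L1 box of HD-ZIP IV factors (4.78% against 2.27%, adjusted p = 2.24e-07) and ABRE (5.29% against 2.40%, adjusted p = 1.14e-08). The site II element (40.4%), the G-box (12.3%) and ABRE (11.5%) were most frequent in the sites of all lists. The auxin response element was in 11.5% of seed coat-only and 6.48% of root-only sites (adjusted p = 2.52e-11), and the root hair element core in 13.1% and 17.03% (Fisher's exact, two-sided, adjusted p = 3.13e-05). The MYB core was in 25.1% and 22.2% (Fisher's exact, two-sided, adjusted p = 0.0119), a direction that turned when the whole site was searched (adjusted p = 0.00718). The AC element (26.8% against 19.3%, adjusted p = 1.29e-11) and the LEAFY motif (7.24% against 4.998%, adjusted p = 0.000478) (Fisher's exact, two-sided) were no longer called with the whole site, where the differences were 0.899 and 0.288 percentage points. Mean GC content was 34.1% in seed coat-only and 31.1% in root-only sites.

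Per-site Fisher's exact tests (two-sided) called the same 2969 and 3041 sites at an adjusted p of 0.0499, and leaving out any one of the 11 lists left 0 calls, because the smallest unadjusted p of 0.00606 needs all of them. Without the 7 DPA pool there were 4722 seed coat-only and 3565 root-only sites, and the adjusted p rose to 0.134 for photosynthesis, 0.0624 for proanthocyanidin and 0.0624 for root hair genes, and without non-hair replicate 3 to 0.0640 for root hair genes. With the same number of peaks in every list, proanthocyanidin (0.128) and root hair genes (0.114) were not called, and with the best 12375 peaks per list the floral organ list alone was. Of all separating sites, 2142 lay in the upper ranks (percentile of at least 50 in each list of their group), 896 of them seed coat-only. Root-only sites had to meet this limit in 8 lists and seed coat-only sites in 3.

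**Figure D2:**
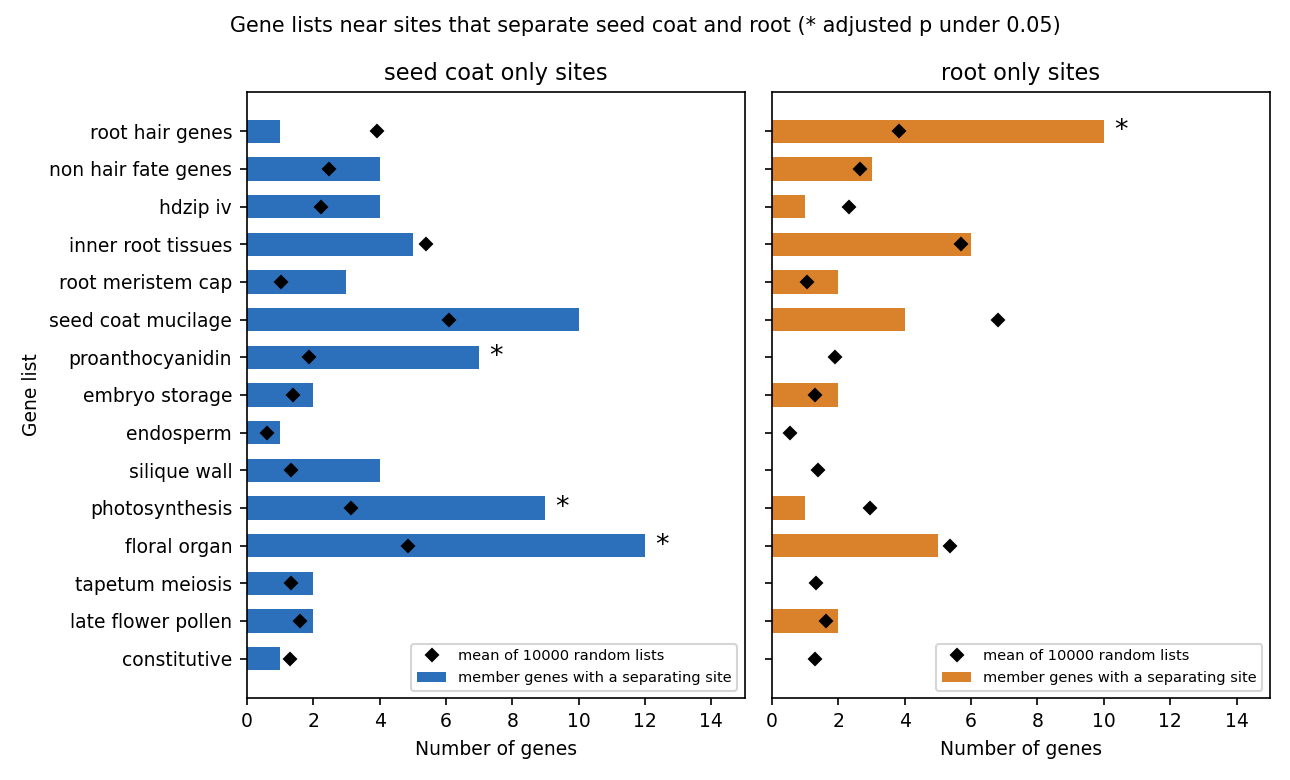
Number of member genes with a seed coat-only site (left) or a root-only site (right), for each gene list except the transgene promoters on the vertical axis. Diamonds stand at the mean of 10000 random lists and asterisks at adjusted p under 0.05. Floral organ genes had 12 with a seed coat-only site against a random mean of 4.85, and root hair genes 10 with a root-only site against 3.83.

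**Figure D3:**
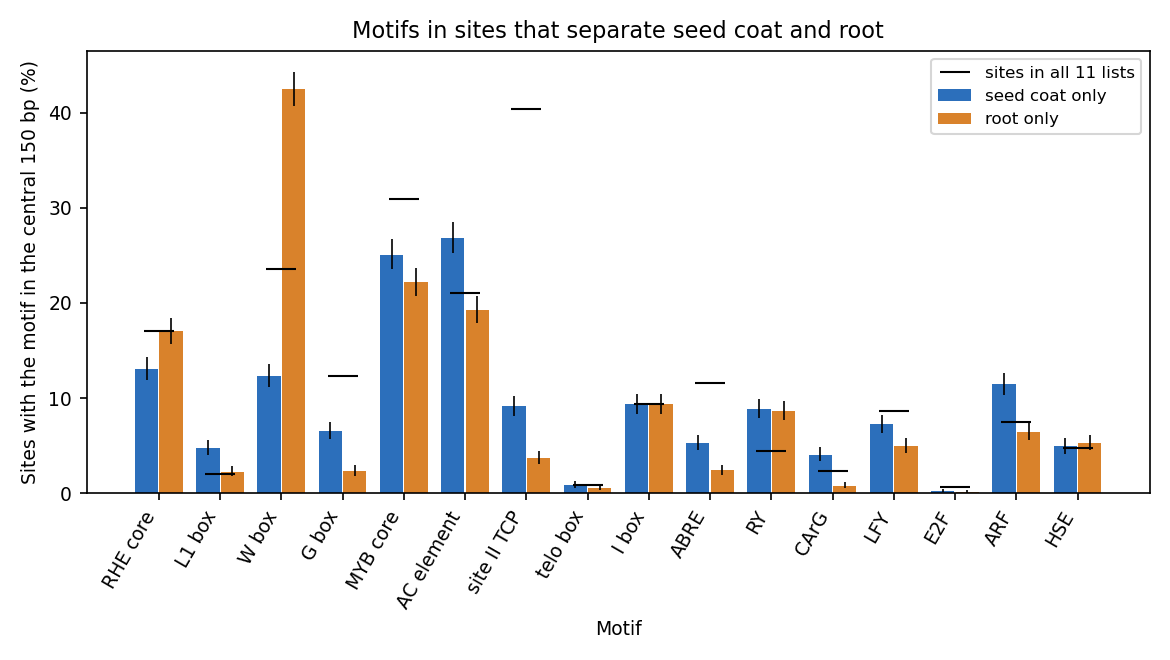
Percent of seed coat-only and root-only sites with each of the 16 motifs in the central 150 bp, with exact 95% binomial intervals as bars and black dashes for sites in all 11 lists. The W-box stands at 42.5% of root-only sites and 12.4% of seed coat-only sites.

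Seed coat and non-hair cells were labelled through the same GL2 promoter, and the series design describes both as epidermal. Proanthocyanidin genes, of the inner layer, were called here, and mucilage and seed coat epidermis genes were not. These lists were not tested against each other, so the calls do not show which layer of the seed coat was captured. Root hair genes were the most enriched list: 13 of 28 had a site in all 4 non-hair lists and in no seed coat list (random mean 4.29, adjusted p = 0.0064, permutation, one-sided), although these lists come from the cells that form no hairs. There were 3732 seed coat-only and 3966 non-hair-only sites, and the highest count of both directions in any of the other 34 splits was 1217 against the real 7698. Again MRH1 (97.6), RSL3 (88.9), RHD2 (86.7) and EXPA18 (83.3) had the highest-ranked non-hair-only sites among root hair genes. RHD6, the bHLH gene that starts hair formation, had instead a seed coat-only site at percentile 40.9.

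Floral organ genes (14 of 23, random mean 6.24, adjusted p = 0.0096, permutation, one-sided) and proanthocyanidin genes (7 of 13, random mean 2.48, adjusted p = 0.032) were called for seed coat-only sites, and photosynthesis genes were not (9 of 30, random mean 3.97, adjusted p = 0.08). Mucilage genes had 12 of 30 (random mean 7.95, adjusted p = 0.373, permutation, one-sided), with MYB61 at 97.8, STK at 96.5 and AP2, a regulator of floral organs and the seed coat, at 97.0, the last with a non-hair peak 50 bp away. High-ranked seed coat-only sites lay near the homeodomain gene BLH2 (99.6), the wax exporter gene ABCG12 (chromosome 1, 19101541 to 19101950, 99.4), the flowering gene AGL20 (chromosome 2, 18811661 to 18811950, 99.3) and ETC3, a single-repeat MYB gene of epidermal patterning (chromosome 4, 459481 to 459810, 98.9). The W-box was in 44.0% of non-hair-only and 12.1% of seed coat-only sites (Fisher's exact, two-sided, adjusted p = 2.29e-220), and the CArG box in 0.857% and 3.70% (adjusted p = 3.10e-17).

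Without the pooled lists 12997 sites separated the groups, 7949 of them seed coat-only, and without the 7 DPA pool alone seed coat-only sites outnumbered the rest, 5855 to 4618. The adjusted p of proanthocyanidin genes (permutation, one-sided) rose to 0.0587 without the 4 DPA pool, 0.198 without the 7 DPA pool and 0.0819 with equal numbers of peaks. With the best 12375 peaks per list, 4944 separating sites were left and only floral organ genes were called, root hair genes having an adjusted p of 0.783 (permutation, one-sided).

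The comparison of hair with non-hair cells asks where the regulatory DNA of the 2 epidermal cell types of the root differs. Both hair lists come from 7-day seedlings. Of the non-hair lists, replicate 2 is from 7-day and replicates 1, 3 and 4 are from 10-day seedlings. Cell type and seedling age therefore cannot be fully told apart here. Non-hair replicate 2 had a mean Jaccard index of 0.480 with the hair lists and 0.455 with the other non-hair lists. Few of 36188 sites separated the cell types, with 17474 in all 6 lists. Both hair lists and no non-hair list held 282 sites, and all 4 non-hair lists and no hair list held 641. RHD6 (AT1G66470) had the 1 hair-only site among root hair genes, within 400 bp upstream of its TSS at chromosome 1, 24794781 to 24795210, at percentile 6.82. LRL2, a bHLH gene of root hair growth, had a non-hair-only site at 7.97. No gene list was called (0 of 32 tests with an adjusted p or an unadjusted p under 0.05, permutation, one-sided), and non-hair fate and HD-ZIP IV genes had no separating site.

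Other list members with a non-hair-only site were TMO5, a bHLH gene of the vasculature (21.4), GLK2, a regulator of chloroplasts (39.8, with a hair peak 90 bp away), and UBQ10, in its 3-prime UTR (chromosome 4, 2720121 to 2720430, 13.9). The highest-ranked hair-only sites lay near AT3G15300 (94.7), ASG1, ERF15, BT1, AT4G28840, AT1G73390, BAP1 and AT4G30490, and the highest-ranked non-hair-only sites near AT2G44660 (99.2), the jasmonate repressor gene JAZ1 (98.4), AT5G67411, ATCTH, AT1G06070, AT3G52360, AT3G15300 and FLA18. For 7 of 8 in each direction a peak of the other cell type lay between 10 and 90 bp from the site, AT4G30490 and AT3G52360 being the exceptions. At AT3G15300 both cell types had a site, at chromosome 3, 5149221 to 5149450 in hair and 5149481 to 5149670 in non-hair lists. Over all sites, 17.02% of hair-only and 14.04% of non-hair-only sites had such a near peak.

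Separating sites were mostly low-ranked, with a median rank percentile of 15.2 for hair-only and 25.6 for non-hair-only sites. A non-hair-only site needs a peak in 4 lists and a hair-only site in 2, so the directions are not compared on equal terms. Sites in all lists stood at 60.4 in the hair and 62.2 in the non-hair lists. Whether the contrasts in position, motif and GC content follow from low rank or from the unequal numbers of lists was not tested. Hair-only sites were mostly intergenic (63.1%). Non-hair-only sites lay more often within 400 bp upstream of a TSS (32.6% against 23.0%), in 5-prime UTRs (17.5% against 4.96%) and in coding exons (8.11% against 1.42%). Non-hair-only sites more often held the MYB core (37.8% against 20.6%, adjusted p = 2.38e-06), the G-box (13.6% against 3.19%, adjusted p = 2.38e-06), ABRE (11.7% against 2.48%, adjusted p = 5.63e-06) and the root hair element core (24.2% against 14.5%, Fisher's exact, two-sided, adjusted p = 0.00351). The G-box, ABRE and root hair element core share bases, so their differences are not independent, and the core was not tested apart from the G-box. Hair-only sites more often held the L1 box (4.96% against 1.25%, Fisher's exact, two-sided, adjusted p = 0.0048). Mean GC content was 30.0% in hair-only and 37.7% in non-hair-only sites.

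With 15 splits of the 6 lists no share under 0.05 is possible, and the split of non-hair replicates 3 and 4 from the rest gave 826 sites against the real 923. With equal numbers of peaks per list the direction turned, to 480 hair-only and 425 non-hair-only sites, and the total rose to 1521 without non-hair replicate 2, 2116 without hair replicate 1 and 2271 without the hair pool.

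The comparison of whole root with each epidermal cell type asks which open sites belong to other tissues of the root. Both whole root lists, like the hair lists, come from 7-day seedlings, while non-hair replicates 1, 3 and 4 come from 10-day seedlings. Sites in both whole root lists and in no non-hair list numbered 1192, with 1002 in the reverse direction. Inner root tissue genes had 6 of 30 members with a whole root-only site against a random mean of 2.46, the lowest p of the 16 lists for whole root-only sites, though it did not pass the correction (unadjusted p = 0.0246, adjusted p = 0.394, permutation, one-sided). They were the cytokinin receptor gene WOL (chromosome 2, 370941 to 371090, percentile 53.7), SHR, the GRAS factor of the endodermis (chromosome 4, 17690961 to 17691270, 41.1), MGP (27.4), PHB (18.8), MYB36, an endodermal MYB gene (17.2), and LHW (13.5).

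Against hair cells, 1876 sites were whole root-only and 1069 hair-only. The lowest p for whole root-only sites was that of tapetum and meiosis genes, 3 of 9 (DMC1, EMS1 and SPO11-1, random mean 0.889, unadjusted p = 0.0473, adjusted p = 0.746, permutation, one-sided), followed by floral organ genes with 5 of 15 and constitutive genes with 3 of 9 (adjusted p = 0.746, permutation, one-sided, for each). Inner root tissue genes had 6 of 28 (random mean 3.69, adjusted p = 0.899, permutation, one-sided), namely WOL, the HD-ZIP III gene ATHB8 (53.4, with a hair peak 30 bp away), SHR, MGP, PHB and LHW. Among root hair genes, RHS12 and the channel gene CNGC14 had hair-only sites, at 15.2 and 9.86, and LRL2 a whole root-only site at 20.2. No list was called in either comparison (0 of 32 each, with 2 and 1 unadjusted p under 0.05). Non-hair-only sites included an intron site of GL2, the HD-ZIP factor gene of non-hair fate (AT1G79840, chromosome 1, 30037041 to 30037390, 51.7). The same interval was hair-only against whole root at 11.3. The transgene promoters with a non-hair-only site were GL2 and UBQ10 (2 of 4, unadjusted p = 0.0206, adjusted p = 0.394, permutation, one-sided).

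The highest-ranked whole root-only sites against non-hair cells lay near the trihelix gene GT2 (97.3), the calcium pump gene ACA8 (96.4), ERF15, BT1, AT4G28840, TBL27, AT5G02220 and ATG8E, and the non-hair-only sites included those near AT4G34180 (98.4), BTI1, AT4G22610, AFP1, AT1G70790, BGLU45 and BBX28. Against hair cells they lay near GT2, the abscisic acid phosphatase gene ABI1 (96.5), ACA8, TGA1, AT3G52360, AT5G03220, UCC2 and AT5G61590, and the hair-only sites included those near AT4G34180 (98.2), AT3G14380, AT5G50760, ERD6, AT1G30700, AT2G44660 and BGLU45. Of the 8 best-ranked sites of each set, a peak of the other group lay within 10 to 90 bp for all 8 of the first, 7 of the second and 6 of each of the others. Over all separating sites the share with a peak within 100 bp was between 7.89% and 11.6%.

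The W-box was in 34.8% of non-hair-only against 13.4% of whole root-only sites (Fisher's exact, two-sided, adjusted p = 3.49e-31) and in 37.8% of hair-only against 15.2% of whole root-only sites (adjusted p = 2.93e-41). The MYB core was in 38.1% of non-hair-only and 19.8% of whole root-only sites (Fisher's exact, two-sided, adjusted p = 1.79e-20). Without whole root replicate 1 or 2 the totals rose from 2194 to 5566 and 4008 against non-hair, and from 2945 to 6825 and 5939 against hair (4857 without hair replicate 1 and 5075 without the hair pool). The direction against hair turned with equal numbers of peaks per list, to 1328 whole root-only and 1473 hair-only sites, and that against non-hair without non-hair replicate 2 (1337 and 1401) or with 7-day seedlings only (2751 and 2798).

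**Figure D4:**
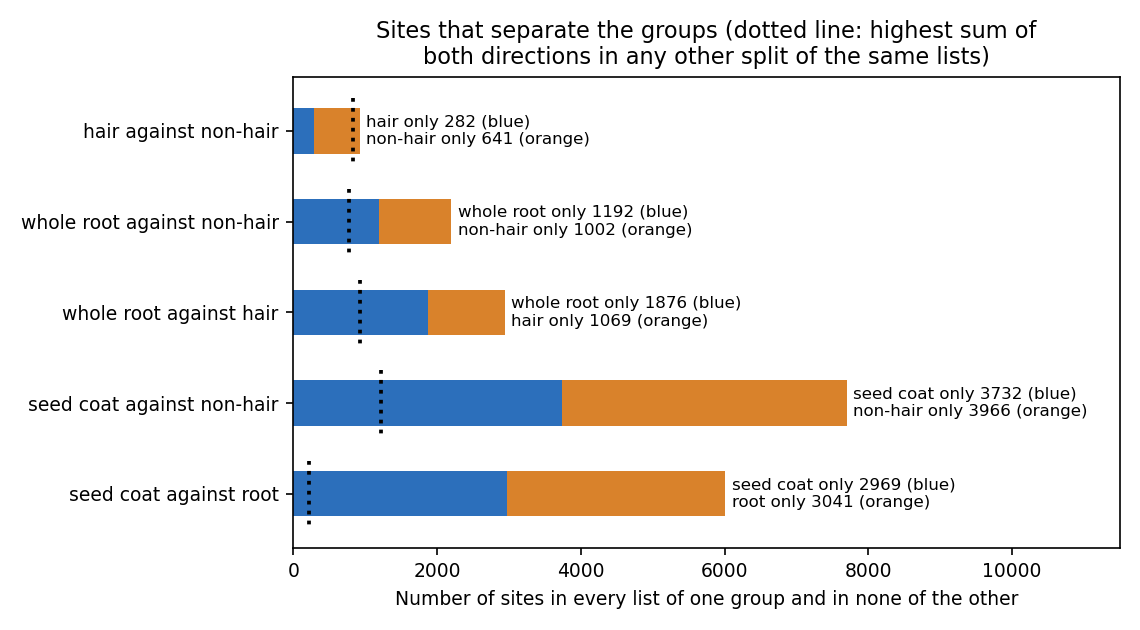
Number of sites in every list of one group and in none of the other, as stacked bars for both directions of each comparison. A dotted line marks the highest sum in other splits of the same lists (100 drawn splits for seed coat against root). Seed coat against root gives 6010 against 220 in the highest other split, and hair against non-hair 923 against 826.

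The comparison of 4 with 7 DPA follows the seed coat as it develops. Sites in both 4 DPA lists and not in the 7 DPA pool numbered 4343, and 3210 were in the 7 DPA pool alone, with 21252 in all 3 lists. Lists of the same stage also differed: 4161 sites of 4 DPA replicate 1 were not in the 4 DPA pool, and 2520 the reverse. The 7 DPA pool lacked 7189 sites of replicate 1 and 5922 of the 4 DPA pool, which lacked 4151 and 4525 of its sites. A 7 DPA-only site needs a peak in a single list, so differences between lists of any stage enter these counts. Embryo and storage genes had 6 of 11 members with a 7 DPA-only site (random mean 1.45, percentile 99.9 among random lists): the 2S albumin gene SESA4, WOX2, the embryo regulators LEC1, LEC2 and FUS3, and BZIP67. With a 4 DPA-only site there were 3 of 11, DOG1, SESA1 and WOX8 (random mean 1.97, percentile 69.15). The best 7 DPA-only site of each gene stood at percentile 63.4 for SESA4, 49.9 for WOX2, 39.7 for LEC1 (AT1G21970, chromosome 1, 7729621 to 7729770, within 400 bp upstream of the TSS), 25.5 for FUS3, 16.9 for BZIP67 and 5.98 for LEC2. Silique wall genes had 5 of 8 with a 4 DPA-only site (random mean 2.68, percentile 92.4).

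These were SHP1 (96.3, with a 7 DPA peak 50 bp away), SHP2 (chromosome 2, 17819781 to 17819930, 95.3), IND, RPL and FUL. Proanthocyanidin genes were low in both directions, with 1 of 13 each (TT7 at 4 DPA and TT10 at 7 DPA, percentiles 1.33 and 4.35 among random lists). Floral organ genes had 10 of 23 with a 4 DPA-only and 8 of 23 with a 7 DPA-only site (69.7 and 63.8). AG, ANT and AP1 had one at each stage, those of AG and ANT within 30 and 70 bp of a peak of the other stage. Photosynthesis genes had 2 of 30 with a 4 DPA-only site (percentile 1.95) and 5 of 30 with a 7 DPA-only site (69.7). Among mucilage genes 9 and 8 of 30 had a 4 DPA-only and a 7 DPA-only site (13.9 and 28.5). PRX36, the peroxidase gene that weakens the outer wall of mucilage cells, had a 7 DPA-only site within 400 bp upstream of its TSS (chromosome 3, 18942841 to 18942990) at percentile 91.2, and NAC2 a 4 DPA-only site at 94.7. HD-ZIP IV genes had 5 of 12 with a 7 DPA-only site (84.1), ATML1, HDG2, HDG11, HDG12 and ANL2, and 4 of 12 with a 4 DPA-only site (40.7), ATML1, ANL2, HDG4 and PDF2.

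The highest-ranked 4 DPA-only sites lay near the trehalose phosphatase gene TPPG (99.2), AT3G62070, BCA4, the proton pump genes HA11 and HA3, BGAL2, GATA1 and AT1G75880. The 7 DPA-only sites were led by AT2G07835 (99.9), which lies in a nuclear copy of organelle sequence, GC5 (chromosome 1, 30035141 to 30035350, 99.5), whose site is in the upstream window of GL2, AT2G01008, GH3.9, BCA4, AT5G56260, AT2G16890 and PLP4. For 5 of the first 8 and 3 of the second a peak of the other stage lay within 10 to 70 bp, and over all sites for 7.69% and 13.7%. Both BCA4 sites had such a peak, as did the GC5 site, with a 4 DPA peak 10 bp away. The upstream window of GL2 also held 4 DPA peaks, the best at rank 28 in replicate 1 and rank 4 in the pool. Site II elements were in 17.9% of 4 DPA-only sites (95% interval 16.7 to 19.0) and 5.11% of 7 DPA-only sites (4.37 to 5.93), and the G-box in 8.45% and 2.71%.

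With a single 7 DPA list, a test over the 3 splits of the lists could not pass 0.05, and none was run. The total of 7553 rose to 11606 without the 4 DPA pool, and with equal numbers of peaks per list the direction turned, to 3201 and 3649.

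Open and unopened flowers were compared to follow the flower as it matures, from a single library each and at unknown depth. Floral organ genes had 15 of 19 members with an unopened-only site (random mean 9.63, percentile 99.4 among random lists) and 4 of 19 with an open-only site (7.83, percentile 1.25). There were 8601 shared, 3114 open-only and 4416 unopened-only sites. Unopened-only sites lay near the meristem identity gene AP1 (87.1), AG (73.0), SEP3 (69.4), SPL (60.5), SEP4, ETT and BOP2, while SPT, SEP3 and BOP1 also had open-only sites. Photosynthesis genes had 3 of 31 with an unopened-only site (random mean 9.94, percentile 0.07).

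The root meristem genes PLT1, PLT3 and ACR4 all had unopened-only sites (3 of 3, percentile 97.0), as did 4 of 5 silique wall genes (88.5) and 8 of 13 inner root tissue genes (89.2). MYB21 and MYB24, MYB genes of stamen maturation, had open-only sites, MYB21 at chromosome 3, 10304921 to 10305070 (93.5) and MYB24 in an intron (49.9), although MYB21 also had an unopened-only site at 7.39. DMC1, the meiotic recombinase gene, had an unopened-only site at 94.0 and an open-only site at 30.8. The other open-only percentiles were 26.9 for photosynthesis (6 of 31), 29.6 for late flower and pollen (2 of 8) and 38.2 for mucilage genes (8 of 20).

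By rank, open-only sites were led by AT1G40104 (99.8) and by AT2G07629, AT2G07689, AT2G07722, AT2G07738, AT2G07719 and AT2G07775, which lie in a nuclear copy of organelle sequence on chromosome 2, then AT5G06980. Of the 100 best open-only sites 15 matched organelle sequence. The unopened-only sites were led by AT3G58760 (99.5), AT5G06980, AT1G40104, BCA4, the spindle checkpoint gene BUB3.1, ECA4, UBC18 and AT1G02290, all 8 with a peak of the open flower list within 30 to 70 bp. Such near peaks lay beside 14.5% of all open-only and 12.6% of all unopened-only sites. The W-box was in 22.8% of open-only (95% interval 21.3 to 24.3) and 16.9% of unopened-only sites (15.8 to 18.1), and the CArG box in 1.77% (1.33 to 2.29) and 3.01% (2.53 to 3.56).

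The promoters carried by the transgenes were examined in the 6.8M lists and, for flowers, in the full-depth lists. In 6.8M lists from plants with the GL2 transgene, the best peak of the GL2 promoter (AT1G79840, chromosome 1, 30036956 to 30041440) ranked between 4 and 121 (141 in the full-depth list of 7 DPA replicate 1), and in whole root and hair lists between 4398 and 9913. The ADF8 promoter (AT4G00680, chromosome 4, 279596 to 281072) ranked 15 and 21 in the hair lists, from plants with the ADF8 transgene, and between 7973 and 21417 in all other 6.8M lists. The UBQ10 promoter (AT4G05320, chromosome 4, 2717977 to 2720308) ranked 55 and 148 in the whole root lists, from plants with the UBQ10 transgene, between 399 and 2821 in the other root lists and between 4051 and 6616 in the seed coat lists (3828 in the full-depth list of 4 DPA replicate 1). ACT2 (AT3G18780, chromosome 3, 6474710 to 6477204), whose promoter is in every plant, ranked between 23 and 226 in the root lists and 1603, 2246 and 3857 in the seed coat lists. In the flower lists, whose plants carry the UBQ10 transgene, UBQ10 ranked 335 (open) and 1234 (unopened), ACT2 2400 and 4268, and neither GL2 nor ADF8 had a promoter peak.

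**Figure D5:**
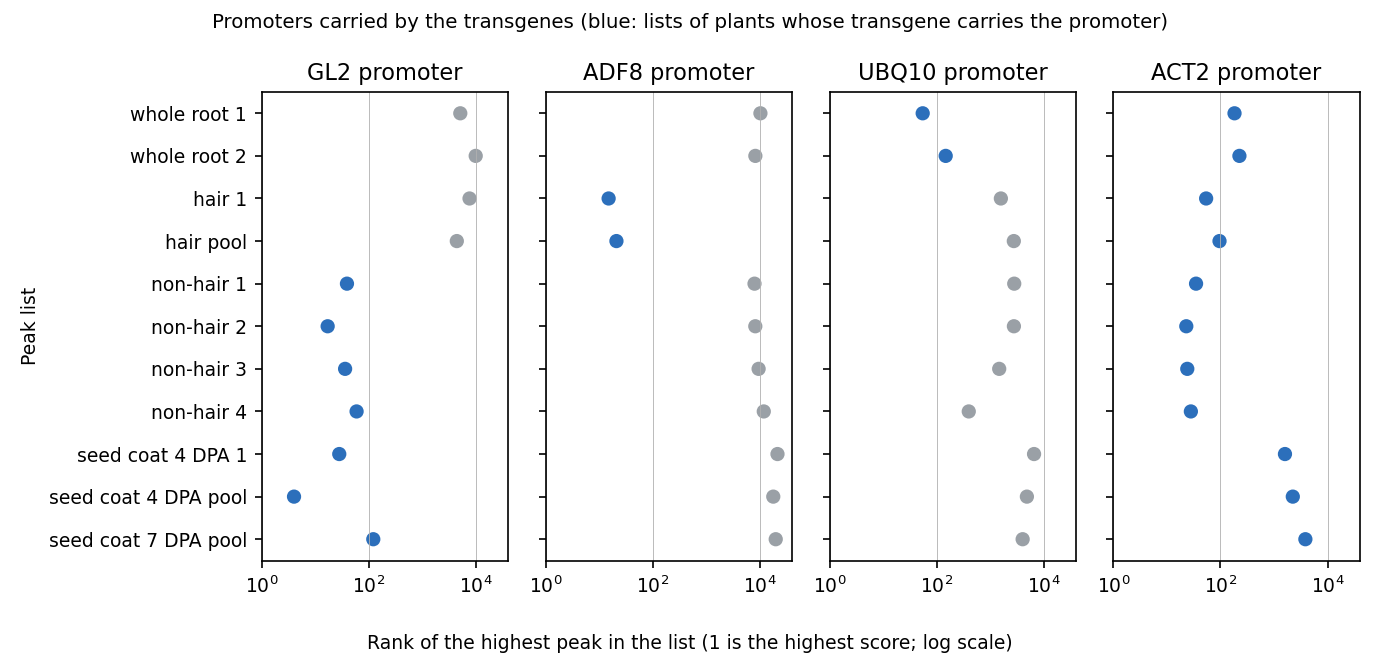
Rank of the best promoter peak (1 is the highest score in the list, logarithmic axis) for GL2, ADF8, UBQ10 and ACT2 in each of the 11 lists at the 6.8M mark, in blue where the plants carry that promoter in the transgene. GL2 ranks between 4 and 121 in blue lists and between 4398 and 9913 in the others.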

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

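Chosen after the results were seen were the tests of extra promoter copies and of unequal list lengths, the shares by seedling age with equal numbers of peaks, the best site per embryo gene, the interval for the embryo maturation genes, and the counts of separating sites in other splits. The full-depth lists hold peaks on the chloroplast and mitochondrial sequences, which no comparison uses and which are given here because any count above 0 in such data was to be reported. The chloroplast and mitochondrial counts were 166 and 55 in whole root, 169 and 201 in non-hair cells, 178 and 84 in hair cells, 251 and 271 in the seed coat at 4 DPA, 242 and 267 at 7 DPA, 244 and 238 in open flowers and 218 and 169 in unopened flowers (replicate 1 of each). No test compared them, and no explanation for them was tested. Among the 4 non-hair lists, 9 measures were examined for a list far from the others, and 0 were beyond Dixon's critical value.

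Other splits of the lists show how many separating sites other divisions give. For seed coat against non-hair, 1 of 35 splits, the real one, gave as many sites (7698, highest other 1217). For seed coat against root 1 of 100 drawn splits, again the real one, did (6010, highest other 220). Both shares are under 0.05 and are the smallest that these splits can give, so a chance division is unlikely to give such counts. Splits cannot tell the cell type from anything else that runs with the groups. The sites called by Fisher's exact test, 6010 in the real split and 0 in the highest other (1 of 100), add no evidence of their own, since any call needs at least 5993 separating sites. For hair against non-hair, the 15 splits, of which 1 gave as many sites, are too few for a share under 0.05 (923, highest other 826).

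In the 6.8M lists, the promoters that drive the nuclear tag ranked near the top of the lists from their own lines. The flower lists, also of the UBQ10 line but at unknown depth, did not show this as clearly. There UBQ10 stood at percentiles 97.1 (open) and 89.95 (unopened), against 88.8 to 98.6 in the 6 root lists of other lines. UBQ10 ranked higher in whole root (the UBQ10 line) than in all 6 other root lists (exact permutation, one-sided, p = 0.0357, 1 of 28 labellings), but these ranks are part of the pattern itself, so they are no evidence for extra copies in the transgene. Extra copies and native activity of the promoter in the captured cells cannot be told apart. Of 9 other constitutive genes, 1 (UBC21, 9.53 points, with a peak in 3 of the 8 root lists) had a gap between whole root and other root lists as large as the 7.34 points of UBQ10. Fewer than 2 was to count against native activity, so by that rule the count of 1 went against it. TIP41 (7.20) and ACT8 (6.98) lay within 1 point of UBQ10, a margin that the rule did not hold. Unlike UBQ10, they were not highest in whole root: TIP41 stood at 78.1 and 80.3 in hair lists, 69.8 and 78.7 in whole root. ACT8 stood at 89.3 in non-hair replicate 4, against 87.1 and 83.1 in whole root. With a single promoter and 2 whole root lists no conclusion is drawn, and for GL2 and ADF8 line and cell type coincide. ACT2, carried by every line, ranked lower in seed coat and flower lists.

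Non-hair-only sites outnumbered hair-only sites, 641 to 282. The hair lists are shorter, and with the same number of peaks in every list the hair-only share rose to 53.0% (480 to 425), so unequal list lengths may account for the direction. Of the sites shared by the other non-hair lists and absent from hair, the 7-day non-hair list, the shortest of the 4, held 61.3%, against between 67.8% and 81.4% for the 10-day lists in order of their lengths, and with equal numbers of peaks 61.6% against between 70.02% and 78.3%. Seedling age may therefore affect the counts, although there is a single 7-day list and a lower share there takes away non-hair-only sites and does not add them. The directions also differ in how many lists must hold or lack a site (4 non-hair, 2 hair), and the effect of that was not tested. A difference between the cell types themselves stays open and was not tested apart from all of these.

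Embryo and storage genes carried 7 DPA-only sites more often than nearly all random lists. Whether weak peaks play a part cannot be told: their sites stood at a median percentile of 21.2 in the 7 DPA list, against 25.5 for all 7 DPA-only sites, but the best site of each gene at a median of 32.6, and the random lists draw on the same 7 DPA-only sites. Embryo nuclei among those captured cannot be judged from maturation genes either, which may not stand for embryos of that age. None of 9 further embryo maturation genes with a site had a 7 DPA-only site (percentile 0, random mean 1.34), as in 21.4% of random lists. The exact 95% interval of that share ends at 33.6%, below the 44.4% (4 of 9) that percentile 95 needs. That bar does not say how many sites embryo nuclei would give, so no conclusion is drawn. At 4 DPA 3 of these 9 genes had a 4 DPA-only site (CLO1, OLEO4 and WRI1, percentile 72.3). Growth of the seed between the stages stays open and was not tested.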

How the results depend on the processing

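Chosen after seeing the data were the limit to upper ranks, absence also from full-depth lists, the removal of organelle-like sites, and gene lists under the alternatives for peaks. Of 382 alternative values, 300 stayed on the same side of their threshold or within range, 62 moved, 19 were weaker and 1 reversed. These verdicts rest on totals for the separating sites; the larger side turned in 18 of 88 alternatives for their counts (2 of 16 for hair against non-hair, 2 of 14 and 2 of 11 for whole root against non-hair and hair, 5 of 16 and 4 of 18 for seed coat against non-hair and root, 3 of 9 for 4 against 7 DPA). The difference in similarity stayed positive throughout (0.0845 to 0.173). Overlap of at least 50% changes nothing by construction, since every peak lies wholly within its site. Of 464 named sites, 389 still separated the groups with equal numbers of peaks, 357 with peaks within 100 bp merged and 198 with the best 12375 peaks. With those best peaks, separating sites numbered 1461 for whole root against non-hair, 1632 for whole root against hair, 4944 for seed coat against non-hair and 4601 for 4 against 7 DPA, and 1 gene list was called for seed coat against non-hair and 1 against root. With equal numbers of peaks 2 were called against root. In the upper ranks alone 108 sites separated hair from non-hair, 203 whole root from non-hair, 280 whole root from hair, 2720 seed coat from non-hair, 2142 seed coat from root, 1281 4 from 7 DPA and 1565 the flowers. Fewer peaks leave fewer sites by construction. Absence also from full-depth lists left 1442 for whole root against non-hair. Fewer lists raise the counts by construction, since fewer must agree: leaving out each list gave 1188 to 2271 for hair against non-hair (2116 without hair replicate 1, 2271 without the hair pool, 1521 without non-hair replicate 2), 2546 to 5566 for whole root against non-hair (5566 and 4008 without whole root replicates 1 and 2), 4857 to 6825 for whole root against hair, with every list left out above 1.5 times the count of 2945, and 10653 to 11606 for 4 against 7 DPA (11606 without the 4 DPA pool). Fisher's exact test then called 0 sites, and between 2 (without the 7 DPA pool) and 5 (without non-hair replicate 1) gene lists were called for seed coat against root, both times with silique wall genes, not called as reported. Without pooled lists there were 2232 sites for hair against non-hair and 12997 for seed coat against non-hair, with 7-day seedlings only 3496 for hair and 5549 for whole root against non-hair, and with presence in at least 3 of 4 non-hair lists 1960. Searching the whole site called 8 motifs for hair against non-hair (5 in the central window) and kept 37 of 43 calls over all comparisons, and of 107 recomputed gene list calls 93 remained. It reversed the MYB core for seed coat against root (adjusted p = 0.00718, Fisher's exact, two-sided, -3.49 points); the cause was not tested. Set against sites in every list, non-hair-only sites called 6 motifs for whole root against non-hair (10 as reported). The full-depth lists held 29250 peaks for whole root replicate 1, 25190 for hair replicate 1 and 32159 for 4 DPA replicate 1, and the depth of the full-depth lists limits the flower comparison, since list lengths there may follow depth (equal lengths gave 3485 open-only and 3493 unopened-only sites).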

Other observations

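The comparisons in this part were chosen after seeing the data. Of the seed coat-only sites against root, 14.7% (435 of 2969, exact 95% interval 13.4 to 16.0) had a peak in the open flower list and 24.1% (715, interval 22.6 to 25.7) in the unopened flower list. Root-only sites had 2.43% (74 of 3041) and 2.53% (77), and sites in all 11 lists 64.7% and 64.3%. Of the 12 floral organ genes with a seed coat-only site, 10 had an unopened flower peak there (AG, AP3, ETT, HEC1, SEP1, SEP2, SEP3, SEP4, SPL and SUP) and 5 an open flower peak (AG, AP3, SEP1, SEP2 and SEP3). The nuclear tag is driven by the GL2 promoter in the seed coat plants and by the UBQ10 promoter in the flower plants.

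Scores in the 6.8M lists are all whole in value but written in 2 formats, between 27.2% and 35.3% of them without decimals and the rest with zeros after the point. Sites matching organelle sequence made up 9 of 3210 7 DPA-only sites, 7 of them among the best 100, and 16 of 3114 open-only sites, 15 of them among the best 100, all 16 on chromosome 2.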
